A study of Mus musculus with 8 samples.

How the data were processed

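RNA from 8 samples of mouse embryonic fibroblasts was measured on 4 two-colour Agilent whole mouse genome oligonucleotide arrays. The samples form 4 groups of 2: WT low, WT high, delN low and delN high density. Groups were taken from the titles and the cell density and genotype characteristics of the labels. The source text of every sample names high density, which conflicts with the titles and the density characteristic for the low-density samples, so it was not used. Replicate numbers follow the order of the samples only. Per the labels' protocols, total RNA was extracted with miRNeasy kits and labelled with the Quick-Amp kit, and the channels were treated as single intensities, not as ratios. The files show 2 slides and 2 scans, with both WT arrays on 1 and both delN arrays on the other, so genotype and slide cannot be separated.

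Per the file headers, spots were quantified with Agilent Feature Extraction 10.5.1.1, which gives the mean intensity, the local background intensity and a processed signal for each dye, and the probe coordinates refer to build mm8. Per the file headers, the processed signal intensity was background subtracted, detrended and dye normalized within each array, and it was not normalized between arrays. The series table, as deposited, holds the same processed signal intensities on a linear scale (100% of its values are equal to those of the array files, with medians per sample of 67.1 to 96.2). No value column was left unmapped (0 columns).

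The array holds 45018 spots. The 1639 control spots were left out after background correction, and 72 to 177 spots per sample marked as outliers by the software were left out too. The remaining 43379 spots hold 41174 distinct probes. Gene names came from the accession that the files pair with a probe (24375 probes), a current symbol in the file (6301), a unique synonym (2426) or else the name in the file (8072), looked up in a gene table of assembly GRCm38.p6 that was used for names only. This gave 27597 names.

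Mean intensities were background corrected with normexp (offset 50), normalized by loess within arrays, with control spots at weight 0, and by quantiles of the average intensity between arrays, and put on a log2 scale with limma 3.58.1 in R 4.3.3, with statmod 1.5.0 and data.table (version 1.17.8). The offset draws log2 differences of dim spots towards 0. Spots of 1 probe were averaged. A probe was kept if both samples of at least 1 group were well above background by the flag of the software, which left 24582 probes. Each gene is represented by the probe with the highest mean over the 8 samples, which gave 16121 genes, of which 28 had 1 missing value. Probes of Lats1, Lats2 and Trp53 that disagree are given separately. A group with a sample not well above background gives only a bound, computed against the higher of the measured value and the lowest value well above background in that sample.

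The 8 channel values were fitted with limma: a mean per group and a dye term, the array as a random block, and empirical Bayes moderation (prior SD 0.0627, prior degrees of freedom 3.13, residual degrees of freedom 3). Calls are two-sided with a Benjamini-Hochberg adjusted p under 0.05. The correlation of the 2 channels of an array was 0.63, estimated from the ratio of the variances of sums and differences of channels. This estimator replaced the consensus estimate of limma after the latter failed on simulated data: with a simulated correlation of 0.63 the consensus gave 0.933 and the estimator used gave 0.625. The consensus on the real data was 0.932, and its use is an alternative chosen after the data were seen.

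The comparisons were high against low density in WT and in delN cells, the difference of these responses, and delN against WT at each density. Density comparisons lie within arrays, and the genotype comparisons lie between arrays and slides. Median standard errors of a log2 fold change were 0.038 within a genotype, 0.054 for the difference of responses and 0.063 between genotypes. The SD of log2 values was 0.129 between spots of a probe in 1 sample (121 probes with 3 or more spots) and 0.073 between samples of a group for single spots of these probes. The first value also holds differences between positions on the array, which cancel in the second. The comparison thus cannot show whether the samples of a group vary beyond technical noise. Counts of genes at least 2-fold apart with the samples of a group taken as 1 are given beside the calls of the 4 pairwise comparisons. Overlaps of genes at least 2-fold changed are given beside the product of the list sizes over the genes tested.

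The fit was tested on simulated data with 16093 genes. In the WT density comparison, 31, 49, 50 and 50 of 50 genes changed by 0.25, 0.5, 1 and 2 (log2) were called in the right direction, with 12 of 15893 unchanged genes called. At low density between genotypes the numbers were 0, 30, 48 and 50, with 3 of 15893 called. In the list test, a list shifted by 0.3 was called, as were 0 of 33 others. The simulated genes varied independently of each other, so this does not cover lists whose genes are correlated.

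Before the data were examined, 34 gene lists were fixed: 24 of pathways, 2 controls (housekeeping and sex chromosome genes) and 8 of markers of other cells that an embryo culture could hold (macrophage, endothelial, epithelial, skeletal muscle, neural and glial, adipocyte, chondrocyte and erythroid). Of 778 listed members 670 were measured. Counts and medians of a list use the fitted values of all measured members, also where a group was not above background, as for Lats2 and Cdkn1a in delN cells. Lists were tested with camera on values whitened for the array block, with a preset correlation between genes of 0.01 and again with the estimated one, adjusted over the lists within a comparison (170 tests in all, of which 57 passed with the preset correlation and 0 with the estimated one). The form with the estimated correlation also takes its p-values from the 3 residual degrees of freedom. A call lost there is thus not a measure of gene correlation alone. The median and the mean of a list differed in sign in 23 tests, 0 of them among those that passed.

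Named genes were chosen by a rule: Lats1 and Lats2; the 6 highest and 6 lowest log2 fold changes of each pairwise comparison and the 4 highest and 4 lowest of the difference of responses, among called genes with the same direction in both dye orientations, above background in the higher group, and with an ordinary gene name; up to 4 members with the lowest adjusted p of each list described; and always Ccn2, Ccn1, Ankrd1, Yap1, Wwtr1, Cdkn1a, Cdkn2a, Ccnb1, Mki67, Xist and Ddx3y. A few genes that this rule names are not reported here. Other genes are named as chosen after their values were seen, as were the Trp53 probes, the chromosome medians and the figures.

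Alternatives were the processed signals with quantile normalization, no background subtraction, quantile normalization without loess, the series table values as given, no filter or a filter on all 8 samples, every probe tested, no dye term, no array block, the array as a fixed block, a 2-fold threshold, the samples of a group as 1, the estimated correlation between genes, and leaving out each sample. A slide block was not run, since each slide holds 1 genotype. Chromosome medians used 16004 genes with a position, and windows of 20 Mb with at least 20 genes were set against 0.5 times the chromosome median with bootstrap intervals adjusted for the number of windows. Figures were drawn with Python 3.11.15, matplotlib 3.10.9 and pandas 2.3.3.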

Results

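Gene expression was measured in cultured mouse embryonic fibroblasts on a C57BL/6J background. The cells were either wild type for Lats1 (WT) or homozygous for its ΔN allele (delN), and grew at low or at high cell density. Lats1 and its paralog Lats2 are kinases of the Hippo pathway, which holds back the transcriptional co-activators Yap1 and Wwtr1 (TAZ) in crowded cells. The comparisons ask which transcripts change when the cells become dense, which differ between the genotypes, and whether the response to density differs between the genotypes. The 4 groups (WT low, WT high, delN low and delN high) held 2 samples each, and these 8 samples were the 2 channels of 4 Agilent whole mouse genome arrays. Each array carried low-density and high-density RNA of 1 genotype, with the dyes swapped between the 2 arrays of a genotype.

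Between 52.8% and 61.6% of the spots of a sample were well above background, and no spot was saturated. The median spot intensity before background subtraction was 48.7 to 59.5 in Cy3 and 90.0 to 96.1 in Cy5. Across genes, the log2 values of the 2 samples of a group correlated at 0.9971 to 0.9979, against 0.9222 to 0.9497 for the 2 densities of a genotype and 0.9337 to 0.9509 for the 2 genotypes at a density. Genes are not independent replicates, and the number of arrays limits the precision. The labels do not say whether the 2 samples of a group came from separate cultures, so every p-value measures only the spread between these samples. Both WT arrays lay on 1 slide and both delN arrays on another, with 1 scan each, so slide and genotype cannot be told apart in the comparisons between genotypes. Changes are log2 fold changes of normalized intensity, and errors after ± are standard errors of the limma fit unless marked SD, with n = 2 samples per group throughout. The gene lists, the rule for named genes, the thresholds and the tests were fixed before the data were examined, except where stated.

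Lats1 signal at the brightest of its probes (chromosome 10, 7405952 to 7406011, build mm8) was 10.82 ± 0.06 in WT low, 10.46 ± 0.34 in WT high, 9.78 ± 0.19 in delN low and 9.63 ± 0.17 in delN high (log2 intensity, SD, n = 2). This probe was lower in delN cells by −1.03 ± 0.079 at low density and −0.83 ± 0.079 at high density. Another Lats1 probe (7403063 to 7403122) was higher in delN cells at low density, by 1.55 ± 0.067 (adjusted p = 6.66e-06), and was not well above background in WT high. The position of either probe relative to the deleted part is not known here, so they check nothing about the genotype. The density response of Lats1 was −0.36 ± 0.048 in WT, a call that ended without the dye term (adjusted p = 0.0649). In delN it was −0.16 ± 0.048 (adjusted p = 0.0210), and leaving out any of the 4 delN samples ended that call (−0.18 to −0.13, adjusted p = 0.0919 to 0.183).

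Lats2 was present in WT cells (11.33 at low and 10.20 at high density, log2 intensity) and was not well above background in delN cells at its brightest probe (chromosome 14, 56644080 to 56644139). That makes it at least 35.1-fold lower in delN at low density (adjusted p = 1.01e-07) and at least 17.2-fold lower at high density (adjusted p = 1.2e-07). In WT cells Lats2 changed by −1.13 ± 0.029 with density. A probe starting at 56644108 gave at least 16.4-fold and 7.79-fold lower signal in delN at low and high density, and one starting at 56645246 at least 2.98-fold and 1.53-fold. A probe at 56676512 to 56676571, above background in every group, did not show this difference: it differed by −0.0092 ± 0.064 (adjusted p = 0.907) at low and 0.24 ± 0.064 (adjusted p = 0.0156) at high density. The direction for Lats2 turned where the processed signals of Feature Extraction, the array software, made that probe the brightest (0.013 and 0.32).

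**Figure D1:**
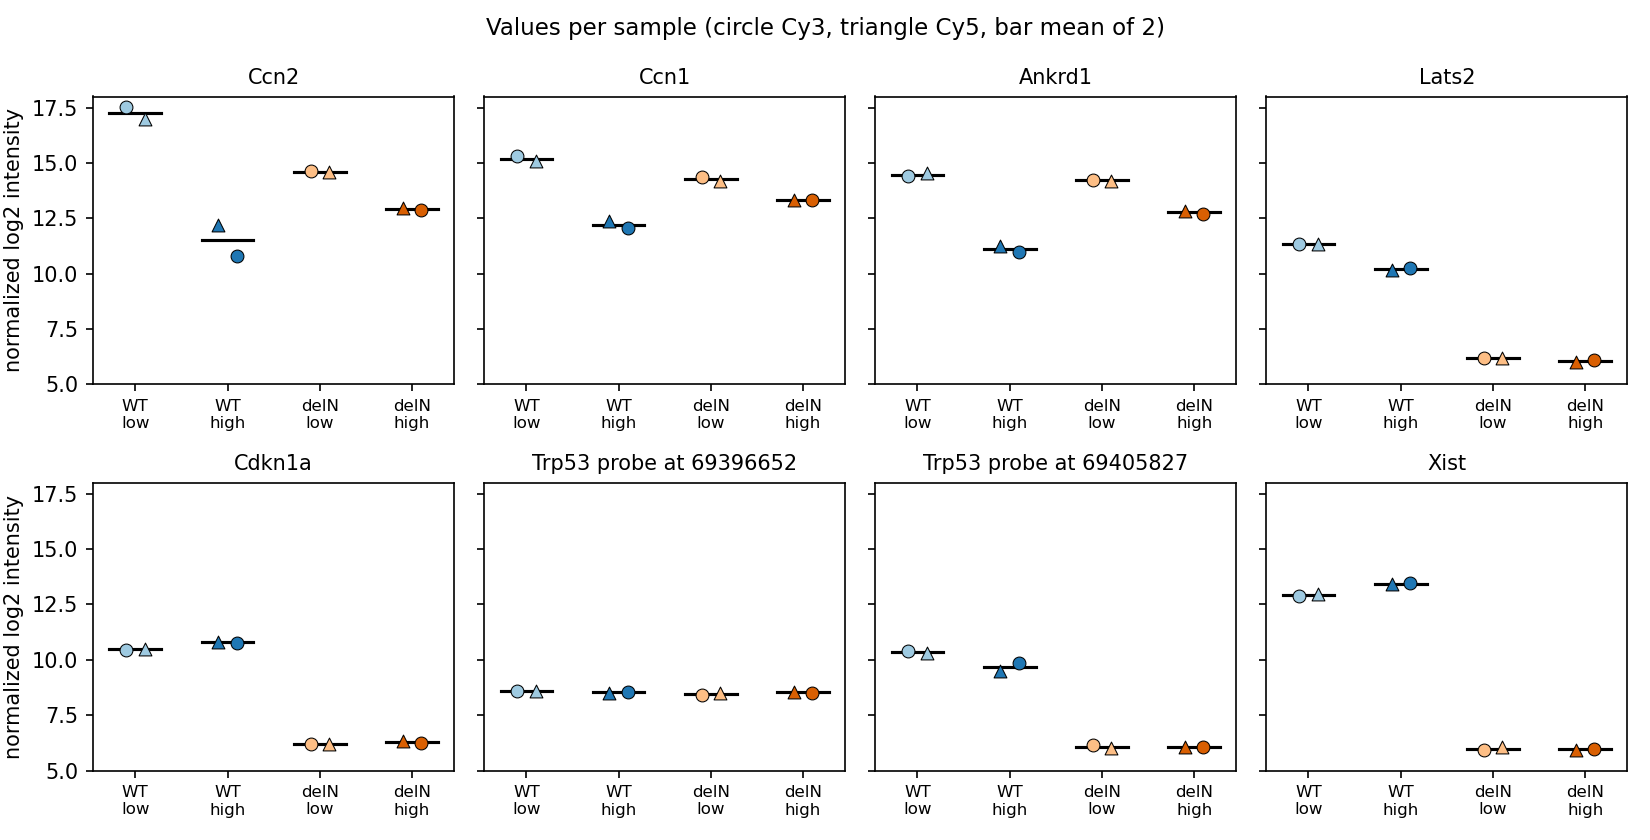
Normalized log2 intensity (vertical axis) of 7 genes in each of the 8 samples, by group (horizontal axis), with circles for Cy3, triangles for Cy5 and a bar at the mean of 2 samples. Ccn2 fell by 5.77 with density in WT and by 1.68 in delN, while Lats2, Cdkn1a, Xist and the Trp53 probe starting at 69405827 sat near background in delN samples, and the Trp53 probe starting at 69396652 differed by −0.13 at low density.

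High density in WT cells lowered Ccn2, Ccn1 and Ankrd1, which are known targets of YAP and TAZ, by −5.77 ± 0.22, −2.98 ± 0.072 and −3.34 ± 0.061. Among the genes that rose most were Lum, a collagen-binding proteoglycan (8.66 ± 0.13), Igfbp5 (6.38 ± 0.075), Penk (5.94 ± 0.034) and Dcn (5.57 ± 0.053), with Lrrn3 and Phex at 5.48 ± 0.10 and 5.43 ± 0.091. Falls were seen for the gap junction gene Gjb2 (−5.20 ± 0.059), the contractile gene Cnn1 (−3.71 ± 0.093) and Slc1a6 (−3.67 ± 0.062). Alkal1 was at least 13.8-fold lower, since 1 of the 2 WT high samples was not well above background (adjusted p = 1.96e-07). Proliferation genes fell together, among them Mki67 (−1.63 ± 0.042) and Ccnb1 (−1.06 ± 0.034), while the CDK inhibitor genes Cdkn1c, Cdkn2a and Cdkn1a rose by 3.34 ± 0.034, 1.64 ± 0.040 and 0.32 ± 0.029. Wwtr1 rose by 0.46 ± 0.028 and Xist by 0.51 ± 0.032, and Yap1 did not pass (−0.033 ± 0.056, adjusted p = 0.614).

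Of 36 genes of DNA replication and the G1/S step, all 36 fell in WT cells (median −1.47, adjusted p = 6.55e-14). Exo1 lay at −1.99 ± 0.028 and Rrm2 at −1.89 ± 0.030. Of 38 genes of G2/M and mitosis, 37 fell and Pttg1 (securin), named after its value was seen, rose by 0.48 ± 0.030. The median of that list was −1.41 (adjusted p = 3.28e-13). Both list calls were lost with an adjusted p = 0.207 with an estimated correlation. Among 24 centrosome genes 19 fell and 5 rose (median −0.68, adjusted p = 7.63e-04), among 14 heat shock genes 13 fell and 1 rose (median −0.63, adjusted p = 7.09e-04), and among 25 immediate early genes 15 fell and 8 rose (median −0.66, adjusted p = 0.0270). These had adjusted p = 0.353, 0.444 and 0.353 with an estimated correlation.

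Smooth muscle genes and other targets of SRF, the factor that follows actin dynamics, fell in 23 of 24 cases (median −1.51, adjusted p = 3.52e-08; adjusted p = 0.353 with an estimated correlation). Fhl2 and Itga5 lay at −2.51 ± 0.050 and −2.18 ± 0.034, and only Mylk, a myosin light chain kinase gene, rose (3.46 ± 0.045). Cholesterol synthesis genes fell in 23 of 24 cases (median −0.67, adjusted p = 2.94e-07; adjusted p = 0.304 with an estimated correlation). Idi1 lay at −1.36 ± 0.031. Genes of the ATF4 and unfolded protein response fell in 19 of 27 cases and rose in 6 (median −0.52, adjusted p = 0.00681; adjusted p = 0.353 with an estimated correlation). The serine and one-carbon enzymes Psat1 and Mthfd2 lay at −1.59 ± 0.032 and −1.48 ± 0.030, and Ddit3, the stress factor CHOP, rose by 1.58 ± 0.038.

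Interferon-stimulated genes rose in WT cells in 32 of 38 cases and fell in 2 (median 1.28, adjusted p = 1.9e-06; adjusted p = 0.353 with an estimated correlation), among them the GTPase gene Igtp (3.41 ± 0.042) and Ifi27l2a (2.28 ± 0.037). Matrix proteases and their inhibitors rose in 17 of 22 cases and fell in 4 (median 0.87, adjusted p = 0.0291), p53 targets rose in 19 of 27 and fell in 4 (median 0.33, adjusted p = 0.0244), and imprinted growth genes rose in 13 of 16 and fell in 2 (median 1.41, adjusted p = 0.00562). Each of these 3 lists had adjusted p = 0.353 with an estimated correlation. Ribosomal protein genes rose in 27 of 32 cases and fell in 1 (median 0.37, adjusted p = 0.00176; adjusted p = 0.498 with an estimated correlation). The list of 22 YAP and TAZ targets as a whole did not pass (median −0.33, adjusted p = 0.0649): 14 fell and 6 rose over all genes, and 14 fell and 7 rose adjusted over the list alone. Collagen and matrix genes went both ways, 21 up and 11 down (median 0.50, adjusted p = 0.191). Hypoxia and glycolysis genes did so too, 12 up and 19 down (median −0.18, adjusted p = 0.119).

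In WT cells 12809 of 16121 genes passed the limma test (7056 up, 5753 down), and 2304 of these changed at least 2-fold (1392 up, 912 down). Taking the 2 samples of a group as repeats of 1 extract (n = 1, no test), 1999 genes changed at least 2-fold in both dye orientations. For every other list named for WT cells, the counts adjusted over the list alone were those over all genes. Calls that single settings ended were the p53 targets (0.35, adjusted p = 0.0618) and ribosomal protein genes (0.20, adjusted p = 0.136) with the series table values, and the proteases with probes above background in all 8 samples (0.80, adjusted p = 0.101), while the YAP and TAZ list passed without WT high replicate 2 (−0.37, adjusted p = 0.0440).

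Among the genes that rose most at high density in delN cells were the matricellular gene Ccn3 (6.41 ± 0.070), Sparcl1 (6.09 ± 0.10), the periostin gene Postn (6.03 ± 0.066) and Abi3bp (5.69 ± 0.049). Penk rose by 5.87 ± 0.034 and Sfrp2, a secreted modulator of Wnt signalling, by 5.69 ± 0.078. The prostaglandin synthase gene Ptgs2 fell (−4.32 ± 0.074), as did the proliferin genes Prl2c5 and Prl2c3, which are near-identical in sequence (−3.78 ± 0.070 and −3.71 ± 0.12). Blnk and Bok fell too (−3.68 ± 0.036 and −3.20 ± 0.028), and so did Ccn2, Ccn1 and Ankrd1 (−1.68 ± 0.22, −0.95 ± 0.072 and −1.44 ± 0.061). Wwtr1 (TAZ) rose by 1.08 ± 0.028, and Yap1 did not pass the test (0.048 ± 0.056). Cdkn2a rose by 0.92 ± 0.040, with Mki67 at −1.64 ± 0.042, while Cdkn1a and Xist were not well above background in both samples of any delN group.

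Replication and G1/S genes fell in all 36 cases (median −1.66, adjusted p = 2.36e-13; adjusted p = 0.213 with an estimated correlation). G2/M genes fell in 37 of 38 cases, each at least 2-fold, with Ccnb1 at −2.45 ± 0.034 and Ect2 at −2.50 ± 0.031, and Pttg1 rose by 0.88 ± 0.030 (median −1.73, adjusted p = 2.36e-13; adjusted p = 0.208 with an estimated correlation). Among centrosome genes 18 of 24 fell and 3 rose (median −0.65, adjusted p = 6.53e-04), among immediate early genes 19 of 25 fell and 5 rose (median −0.99, adjusted p = 6.61e-04), and among heat shock genes 11 of 14 fell and 2 rose (median −0.71, adjusted p = 0.00966). These had adjusted p = 0.387, 0.307 and 0.541 with an estimated correlation.

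Collagen and matrix genes rose in delN cells in 34 of 38 cases, 30 of them at least 2-fold, and fell in 1 (median 1.72, adjusted p = 1.34e-07; adjusted p = 0.213 with an estimated correlation). Mfap4 rose by 5.21 ± 0.041, Dcn by 4.17 ± 0.053 and Col6a3 by 2.89 ± 0.034. All 38 interferon-stimulated genes rose (median 2.47, adjusted p = 4.36e-10; adjusted p = 0.347 with an estimated correlation), among them Ifi27l2a (5.07 ± 0.037), Rtp4 (3.51 ± 0.035) and Stat2 (2.95 ± 0.029), part of the factor that carries the interferon signal. Hypoxia and glycolysis genes rose in 30 of 32 cases and fell in 1 (median 1.15, adjusted p = 1.39e-06; adjusted p = 0.265 with an estimated correlation), with the lactate exporter Slc16a3 at 3.33 ± 0.034 and Bnip3 at 3.00 ± 0.030. ATF4 and unfolded protein response genes rose in 24 of 27 cases and fell in 3 (median 1.29, adjusted p = 1.54e-04; adjusted p = 0.213 with an estimated correlation). Trib3 lay at 3.53 ± 0.054 and Nupr1 at 2.41 ± 0.040. Lyz2, a lysozyme gene abundant in macrophages, rose by 3.99 ± 0.071 in the same cells, though the 8 measured macrophage markers did not pass as a list (median 0.053, adjusted p = 0.967). Chondrocyte markers rose in 8 of 10 cases and fell in none (median 1.18, adjusted p = 0.0214; adjusted p = 0.517 with an estimated correlation). Sox9 lay at 1.73 ± 0.036. Proteases and their inhibitors (16 of 22 up, 4 down, median 1.37, adjusted p = 0.0287) and imprinted growth genes (13 of 16 up, 2 down, median 1.60, adjusted p = 0.0116) rose as lists, with adjusted p = 0.387 and 0.293 with an estimated correlation. SRF targets fell in 15 of 24 cases and rose in 4 (median −0.46, adjusted p = 0.0359; adjusted p = 0.638 with an estimated correlation). The YAP and TAZ list did not pass, with 9 genes up and 11 down (median −0.052, mean 0.11, adjusted p = 0.665), nor did cholesterol synthesis, with 13 up and 8 down (median 0.14, adjusted p = 0.665), or the p53 targets, with 15 up and 10 down (median 0.19, adjusted p = 0.665).

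In delN cells 13673 of 16121 genes passed (7649 up, 6024 down), 3341 of them at least 2-fold (2060 up, 1281 down), and 3011 changed at least 2-fold with the samples of a group taken as repeats of 1 extract (n = 1, no test). For every list named for delN cells the counts adjusted over the list alone were those over all genes. The SRF call ended without delN low replicate 1 (−0.35, adjusted p = 0.0764) and without delN high replicate 1 (−0.40, adjusted p = 0.0676), and with probes above background in all 8 samples it ended (adjusted p = 0.0804) together with that of the proteases (1.14, adjusted p = 0.0639).

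The genotypes shared much of the density response. Genes at least 2-fold higher at high density in both numbered 895 (178 expected if independent), among them Penk, Postn and Dcn, and 520 were at least 2-fold lower in both (72.5 expected), among them Ptgs2, Exo1 and Cep55. At least 2-fold changes in opposite directions numbered 5 (higher in WT) and 31 (lower in WT). Across genes the responses correlated at 0.681.

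**Figure D2:**
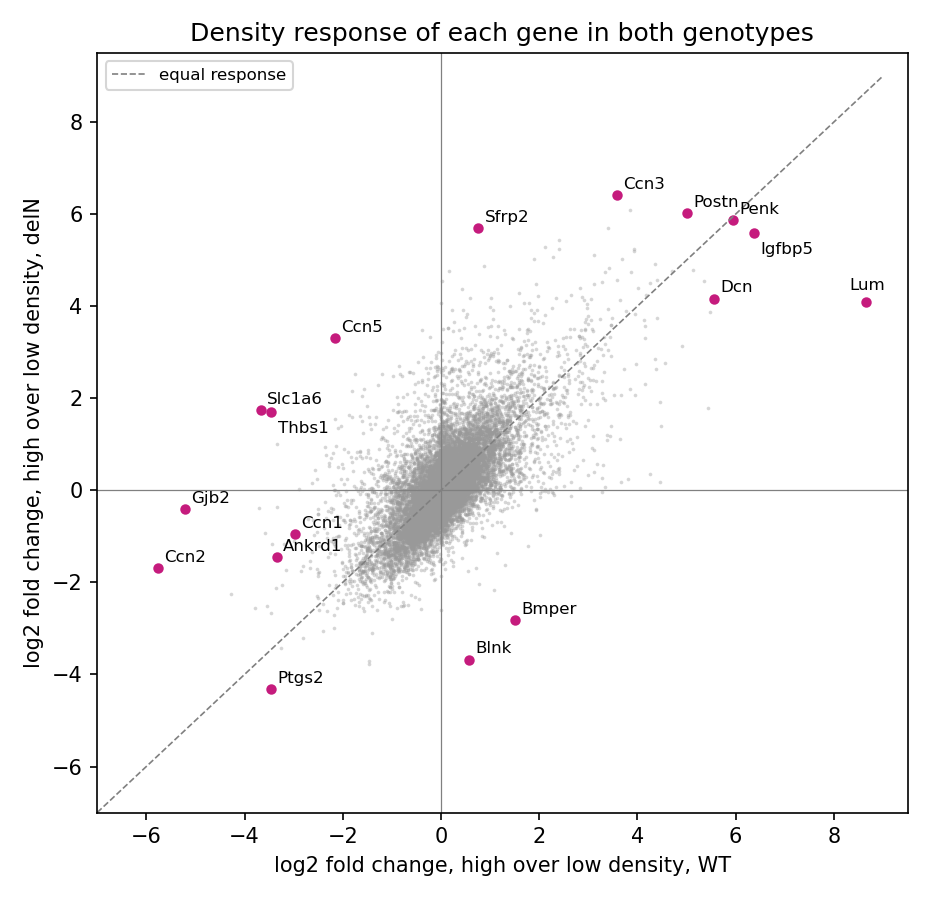
Log2 fold change of high over low density in WT (horizontal axis) and delN cells (vertical axis), with 1 point per gene for 16121 genes and some named genes in colour; the dashed line marks an equal response. Ccn5, Slc1a6 and Thbs1 fell in WT and rose in delN, Ccn2 lay at −5.77 and −1.68, and the value of Sfrp2 in WT is limited by background at low density.

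The difference between the density responses was tested directly, and the values within a genotype printed beside it here were added after it was seen. The matricellular genes Ccn5 and Thbs1 and the transporter gene Slc1a6 fell with density in WT cells (−2.15 ± 0.050, −3.45 ± 0.075 and −3.67 ± 0.062) and rose in delN cells (3.31 ± 0.050, 1.70 ± 0.075 and 1.74 ± 0.062), differences of 5.47 ± 0.071, 5.16 ± 0.11 and 5.40 ± 0.088. The fall of Ccn2, Ccn1 and Ankrd1 was smaller in delN by 4.08 ± 0.31, 2.03 ± 0.10 and 1.89 ± 0.086. Wwtr1 differed by 0.62 ± 0.040, whereas Yap1 (0.081 ± 0.079, adjusted p = 0.386) and Mki67 (−0.0029 ± 0.060, adjusted p = 0.967) did not pass. In the other direction, Bmper, which binds BMP proteins, and Blnk, an adaptor of B cell signalling, rose in WT (1.52 ± 0.033 and 0.57 ± 0.036) and fell in delN, differences of −4.33 ± 0.047 and −4.25 ± 0.050. The G2/M cyclin gene Ccnb1 fell further in delN, by −1.39 ± 0.047, and Cdkn2a rose less, by −0.72 ± 0.056. Sfrp2 (4.93 ± 0.11), Lum (−4.58 ± 0.18) and Epyc (−4.29 ± 0.22) also lay among the most different genes, but with groups not above background (WT low for Sfrp2, delN low for Lum, every group but WT high for Epyc), so these sizes depend on the background.

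YAP and TAZ targets responded higher in delN in 14 of 22 cases and lower in 6 (median 0.66, adjusted p = 0.0246; adjusted p = 0.333 with an estimated correlation), though 1 of the 14, Lats2, was not above background in delN. Amotl2 lay at 2.42 ± 0.076. SRF targets were higher in 22 of 24 cases and lower in none, 23 adjusted over the list alone (median 1.04, adjusted p = 2.27e-07; adjusted p = 0.378 with an estimated correlation). Lmod1 lay at 3.65 ± 0.048, Fhl2 at 2.76 ± 0.070 and Itga5 at 2.18 ± 0.048. Cholesterol synthesis genes were higher in 22 of 24 cases and lower in none (median 1.02, adjusted p = 6.53e-08; adjusted p = 0.254 with an estimated correlation). Sqle lay at 1.38 ± 0.041. Collagen and matrix genes were higher in 28 of 38 and lower in 5, or 29 and 7 adjusted over the list alone (median 1.23, adjusted p = 1.51e-05). Col6a3 lay at 3.26 ± 0.048. TGF-beta response genes were higher in 14 of 20 and lower in 3 (median 0.57, adjusted p = 0.00499). Ltbp2 lay at 3.74 ± 0.047 and Tgfb3 at 3.49 ± 0.045. Both had adjusted p = 0.254 with an estimated correlation.

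ATF4 and unfolded protein response genes responded higher in delN in 26 of 27 cases and lower in 1 (median 1.48, adjusted p = 4.11e-10; adjusted p = 0.229 with an estimated correlation). Nupr1 lay at 2.79 ± 0.056 and Chac1 at 2.77 ± 0.061. Hypoxia and glycolysis genes were higher in 31 of 32 and lower in 1 (median 1.18, adjusted p = 1.7e-10; adjusted p = 0.254 with an estimated correlation). Slc16a3 lay at 3.56 ± 0.048 and Vegfa at 2.19 ± 0.040. Interferon-stimulated genes were higher in 32 of 38 and lower in 4 (median 1.25, adjusted p = 2.27e-07; adjusted p = 0.378 with an estimated correlation). Ifi27l2a lay at 2.79 ± 0.052 and Dhx58 at 2.26 ± 0.052. Lyz2 was higher by 3.00 ± 0.10, with the macrophage list at a median of −0.0042 (adjusted p = 0.834) and Lyz2 at background in WT low. Chondrocyte markers were higher in 7 of 10 and lower in none (median 0.30, adjusted p = 0.0321; adjusted p = 0.539 with an estimated correlation). Col2a1 lay at 2.47 ± 0.056. Proteases were higher in 14 of 22 and lower in 3 (median 0.73, adjusted p = 0.0160; adjusted p = 0.378 with an estimated correlation). Lower in delN were ribosomal protein genes in 25 of 32 cases, with 1 higher (median −0.34, adjusted p = 2.75e-04; adjusted p = 0.576 with an estimated correlation), G2/M genes in 23 of 38, with 3 higher (median −0.34, adjusted p = 9.02e-04; adjusted p = 0.254 with an estimated correlation), and NRF2 targets in 16 of 25, with 6 higher (median −0.52, adjusted p = 0.0499; adjusted p = 0.378 with an estimated correlation).

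**Figure D3:**
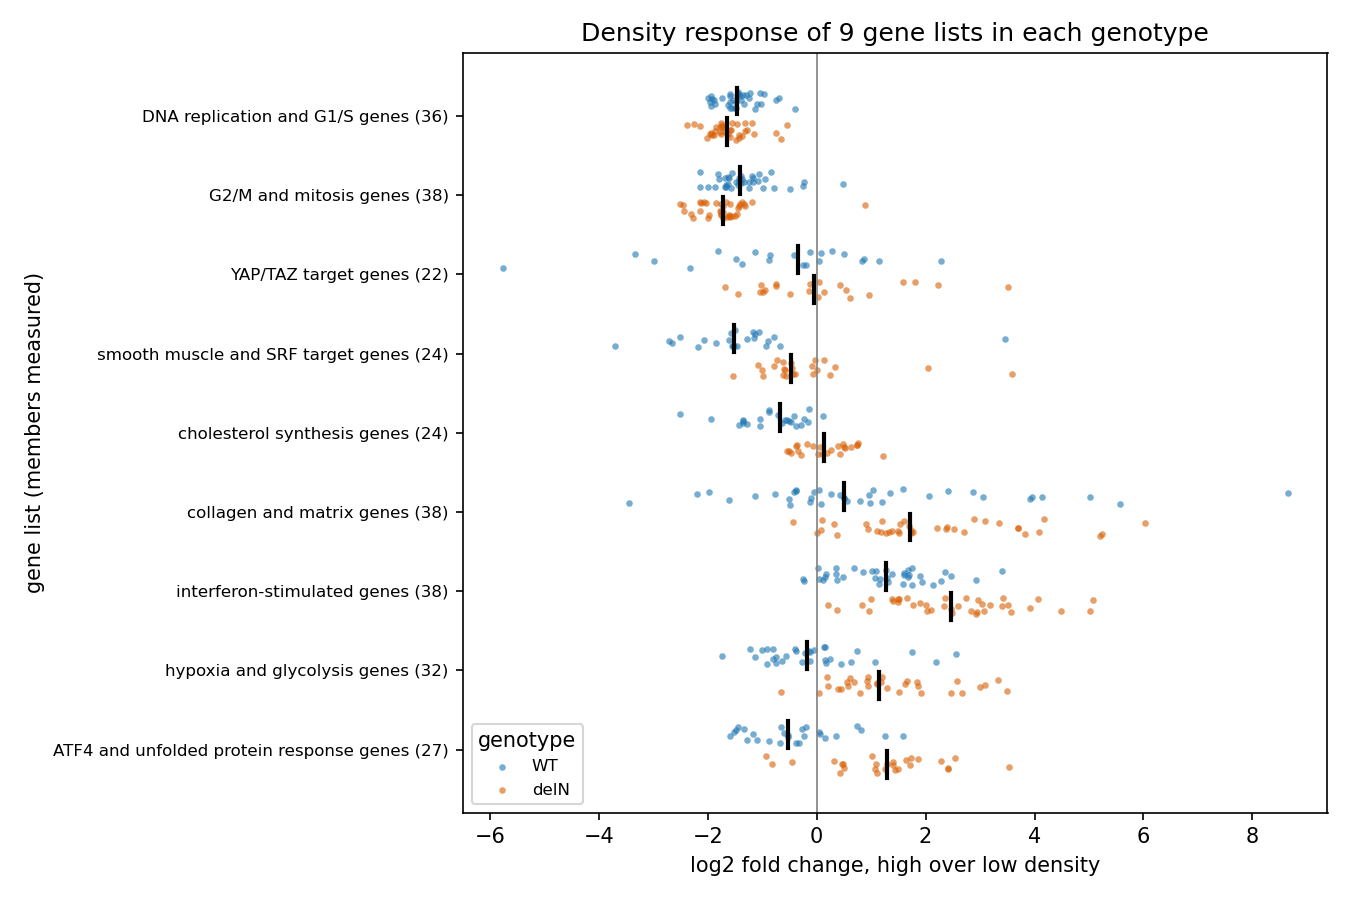
Log2 fold change of high over low density (horizontal axis) for the measured members of 9 gene lists (vertical axis, number of members in parentheses), blue for WT and orange for delN, with 1 point per gene and a bar at the median. Cell cycle medians lay at −1.73 to −1.41 in both genotypes, while ATF4 genes had medians of −0.52 in WT and 1.29 in delN.

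The test of the difference passed for 11783 of 16121 genes (5784 higher in delN, 5999 lower), 1674 of them at least 2-fold (1145 and 529). The interferon median fell to 0.48 with the processed signals of Feature Extraction and 0.47 with the series table values, and the YAP and TAZ call ended with probes above background in all 8 samples (0.36, adjusted p = 0.0518). The NRF2 call ended without WT high replicate 1 (−0.45, adjusted p = 0.0631), WT high replicate 2 (−0.56, adjusted p = 0.0565) or delN high replicate 1 (−0.48, adjusted p = 0.0527), and the chondrocyte call without delN high replicate 1 (0.30, adjusted p = 0.0593).

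Among the largest differences between delN and WT cells at low density were those at Cd34 (6.60 ± 0.055), Nsg1 (5.88 ± 0.061), Erdr1 (5.66 ± 0.057) and Blnk (5.09 ± 0.059), which were higher, and at Gjb2 (−6.73 ± 0.10) and Plac8 (−6.56 ± 0.063), which were lower. The transcription factor gene Tbx1 was at least 39.4-fold higher in delN (adjusted p = 1.01e-07), and Lama5, Inhbb and Mrvi1 were at least 51.1-fold, 45.3-fold and 36.5-fold lower (adjusted p = 1.04e-06, 2.95e-07 and 2e-07), each with 1 group at background. Cdkn1a, the CDK inhibitor gene that p53 activates, was at least 19.6-fold lower (adjusted p = 1.51e-07). Ccn2 and Ccn1 were lower by −2.66 ± 0.36 and −0.93 ± 0.12, Yap1 and Cdkn2a higher by 0.96 ± 0.092 and 1.36 ± 0.066, and Mki67 lower by −0.82 ± 0.069. Ankrd1 did not pass (−0.26 ± 0.10, adjusted p = 0.0601) and passed without delN low replicate 1 (−0.41, adjusted p = 0.00407) and without either WT high sample (−0.26, adjusted p = 0.0262). Wwtr1 was higher by 0.18 ± 0.046 (adjusted p = 0.0138), a call that ended without WT low replicate 1 (0.16, adjusted p = 0.0614) or delN low replicate 1 (0.16, adjusted p = 0.0705).

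Xist, the RNA of the inactive X chromosome, was at least 113-fold lower in delN (adjusted p = 1.01e-07), and the Y-linked genes Eif2s3y and Ddx3y were at least 45.9-fold and 21.8-fold higher (adjusted p = 1.14e-06 and 2.77e-07). Medians over the genes of a chromosome differed from 0 as well: chromosomes 7, 12 and 14 lay at −0.51, −0.45 and −0.34, with 81.8%, 79.8% and 72.5% of their genes lower, and these were the autosomes beyond 0.3 at both densities. The next largest medians were 0.21 for chromosome 8 and −0.20 for chromosomes 10 and 15. The genotype comparisons, and each gene group below, thus also compare cells that differ in sex-chromosome transcripts, in these chromosome medians and in slide.

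Of 27 p53 targets, 23 were lower in delN at low density and 3 higher, or 24 and 3 adjusted over the list alone (median −1.31, adjusted p = 3.3e-06; adjusted p = 0.460 with an estimated correlation). Pmaip1 and Ccng1, which are activated by p53, lay at −2.11 ± 0.055 and −2.00 ± 0.054. SRF targets were lower in 23 of 24 cases, with 1 higher adjusted over the list alone (median −1.49, adjusted p = 1.48e-07), among them Lmod1 (−4.88 ± 0.056) and Itga5 (−3.47 ± 0.056). Collagen and matrix genes were lower in 24 of 38 and higher in 10 (median −0.93, adjusted p = 0.0170), with the basement membrane gene Col4a1 at −4.60 ± 0.12. TGF-beta response genes were lower in 13 of 20 and higher in 3 (median −0.66, adjusted p = 0.0170), cholesterol synthesis genes in 18 of 24 with 2 higher (median −0.56, adjusted p = 0.00458), and ATF4 genes in 20 of 27 with 4 higher (median −0.53, adjusted p = 0.00594). Interferon-stimulated genes were higher in 31 of 38 and lower in 2, or 32 and 2 adjusted over the list alone (median 0.80, adjusted p = 1.48e-07). Cxcl10 lay at 4.32 ± 0.069. Cytokine and NF-kB target genes were higher in 13 of 22 and lower in 4 (median 0.49, adjusted p = 0.0282), with the chemokine gene Ccl2 at 3.77 ± 0.046. Each of these 8 lists had adjusted p = 0.46 with an estimated correlation. The YAP and TAZ list split evenly, 10 up and 10 down, or 10 and 11 adjusted over the list alone (median −0.15, adjusted p = 0.945).

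At low density 11098 of 16121 genes passed (5439 higher in delN, 5659 lower), 1986 of them at least 2-fold (829 and 1157), and 1779 were at least 2-fold apart with the samples of a group taken as repeats of 1 extract (n = 1, no test). The balance of directions depends on the scaling: the series table values move the median of all genes by 0.25 and give 6242 higher and 3355 lower, or 2485 and 1477 at least 2-fold. With them another probe stood for Erdr1 (1.12), while the interferon median rose to 3.04.

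Among the largest differences between delN and WT cells at high density were those at Sfrp2 (9.01 ± 0.13), the class I antigen gene H2-K1 (7.13 ± 0.11), the near-identical H2-Q1 (6.89 ± 0.085) and Slc16a3 (7.07 ± 0.056), all higher, with Chrdl1 at least 185-fold and Slpi at least 159-fold higher (adjusted p = 7.43e-08 and 2.24e-07). Lum was lower by −5.02 ± 0.21, and Mrvi1, Foxc2, Cdkn1a and Epyc were at least 34.2-fold, 23.8-fold, 22.7-fold and 20.9-fold lower (adjusted p = 1.45e-07, 3.92e-07, 1.01e-07 and 1.56e-05), each with delN samples at background. Ccn1, Ankrd1, Yap1 and Wwtr1 were higher in delN by 1.1 ± 0.12, 1.64 ± 0.10, 1.04 ± 0.092 and 0.80 ± 0.046, Cdkn2a by 0.64 ± 0.066, and Mki67 and Ccnb1 lower by −0.82 ± 0.069 and −1.08 ± 0.055. Ccn2 was higher by 1.42 ± 0.36 (adjusted p = 0.0113), a call that ended without delN high replicate 2 (1.18, adjusted p = 0.0593), and the value was 0.86 (adjusted p = 0.0204) without WT high replicate 2. Xist was at least 168-fold lower and Ddx3y at least 37.2-fold higher (adjusted p = 7.03e-08 and 1.33e-07), and chromosomes 7, 12 and 14 had medians of −0.51, −0.56 and −0.38, so the gene groups below move with these differences too.

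All 38 interferon-stimulated genes were higher in delN at high density, 31 of them at least 2-fold (median 2.53, adjusted p = 1.76e-14; adjusted p = 0.391 with an estimated correlation). Ifi27l2a lay at 3.25 ± 0.061. Lyz2 was higher by 5.24 ± 0.12, and the macrophage markers did not pass as a list (median 0.093, adjusted p = 0.937). Hypoxia and glycolysis genes were higher in 30 of 32 cases and lower in 1, or 31 and 1 adjusted over the list alone (median 1.28, adjusted p = 1.5e-09). Ankrd37 lay at 3.39 ± 0.065 and Vegfa at 2.13 ± 0.047. ATF4 genes were higher in 25 of 27 and lower in 1 (median 1.01, adjusted p = 2.34e-07). Chac1 lay at 2.97 ± 0.070. p53 targets were lower in 22 of 27 and higher in 4 (median −1.07, adjusted p = 1.1e-05). Bbc3 lay at −3.08 ± 0.054 and Ccng1 at −2.71 ± 0.054. These 3 lists had adjusted p = 0.328 with an estimated correlation. Cholesterol synthesis genes were higher in 16 of 24 and lower in 3 (median 0.34, adjusted p = 0.00337; adjusted p = 0.463 with an estimated correlation). G2/M genes were lower in 23 of 38 and higher in 2 (median −0.45, adjusted p = 0.00279; adjusted p = 0.391 with an estimated correlation), and replication genes in 19 of 36 with 5 higher (median −0.25, adjusted p = 0.0435; adjusted p = 0.688 with an estimated correlation). SRF targets were lower in 17 of 24 with 4 higher (median −0.61, adjusted p = 0.0369), and ribosomal protein genes in 16 of 32 with 1 higher (median −0.23, adjusted p = 0.0369), both with adjusted p = 0.775 with an estimated correlation. The YAP and TAZ list had 15 genes higher and 5 lower and did not pass (median 0.43, adjusted p = 0.0680).

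At high density 11590 of 16121 genes passed (5612 higher in delN, 5978 lower), 2385 of them at least 2-fold (1249 and 1136), and 2139 were at least 2-fold apart with the samples of a group taken as repeats of 1 extract (n = 1, no test). The series table values move the median of all genes by 0.21 and give 6033 higher and 3504 lower, or 2823 and 1466 at least 2-fold. The calls of replication, SRF and ribosomal protein genes ended without delN high replicate 1 (−0.26, −0.52 and −0.19, adjusted p = 0.0547, 0.0547 and 0.09), those of replication and ribosomal protein genes also without WT high replicate 1 (−0.24 and −0.21, adjusted p = 0.0604 for both), and with the series table values the ribosomal median turned to 0.11 and the YAP and TAZ list passed (0.82, adjusted p = 0.0368).

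Between the densities, the genotype differences overlapped: 488 genes were at least 2-fold higher in delN at both (64.2 expected if independent) and 512 at least 2-fold lower at both (81.5 expected), with 9 and 33 in opposite directions. The 2 differences share arrays, and simulated groups without a genotype effect gave a correlation across genes of 0.630 by themselves, against 0.648 measured. The covariance separated these cases, at 0.00614 simulated (mean of 20 draws, with 0 genes called at both densities on average) and 0.422 measured. The simulation held no slide effect, which both differences would share, so it does not tell genotype from slide.

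**Figure D4:**
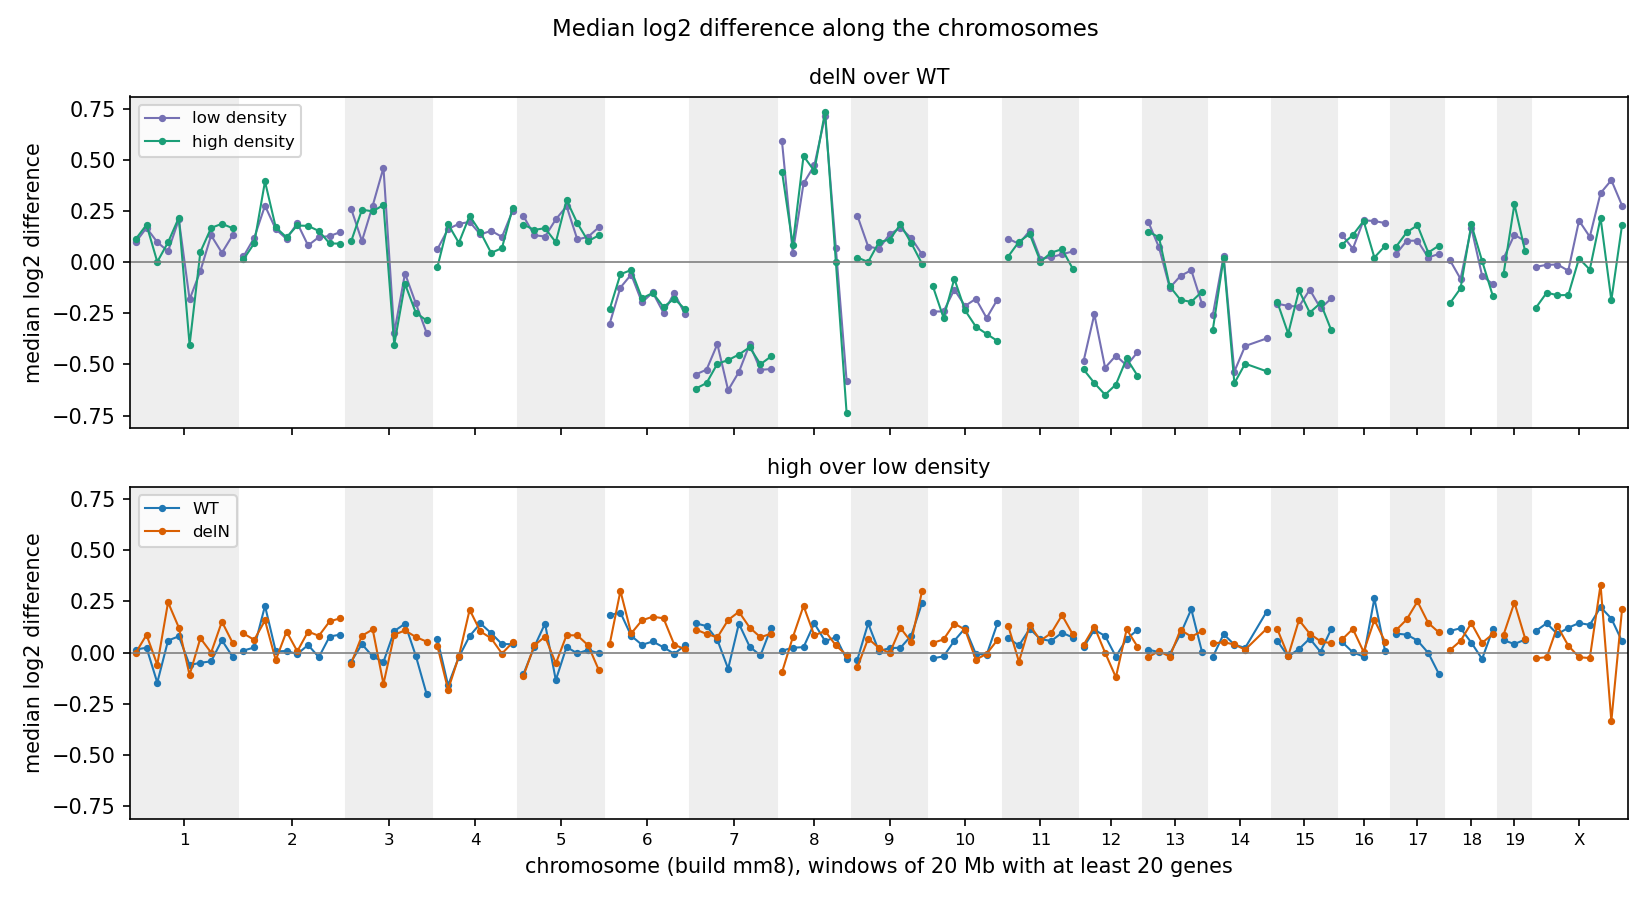
Median log2 difference of the genes in windows of 20 Mb with at least 20 genes along each chromosome (horizontal axis, build mm8), delN over WT at each density in the upper panel and high over low density in each genotype in the lower panel. Chromosomes 7 and 12 lay below 0 in delN over WT at both densities (−0.51 and −0.45 at low density over the whole chromosome), and no autosome had a whole-chromosome median beyond 0.16 between densities.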

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

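The density responses in this part stood out because they differed between the genotypes in a direct test of that difference, and the p53 targets and the chromosomes, which are differences between genotypes, are weighed beside them. The bound of 4-fold for single genes, the patterns weighed, the second test of macrophage genes, the bound used for Xist and the test of chromosome windows were chosen after the values were seen, and the other tests before their results.

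Interferon, hypoxia and ATF4 genes responded higher to density in delN than in WT cells, with list medians of the difference of 1.25, 1.18 and 1.48 that did not pass with an estimated correlation (adjusted p = 0.378, 0.254 and 0.229). A dye bias common to all arrays cancels in this difference, so comparing the dye orientations could not test it. A dye bias that differs between the arrays of the genotypes would push the orientations apart. Medians of at least 1.12 in either orientation alone argue against that as the whole cause. Normalization as the whole cause is argued against by lowest medians over 4 normalizations of 1.04 for hypoxia and 1.36 for ATF4 genes. For interferon genes the lowest median was 0.47, between the bounds set before the test, so normalization stays open for part of that difference. Of 8 abundant macrophage genes 3 (Fcer1g, Coro1a and Mpeg1) were well above background in delN high, 1 more than the bound set before the test. In the test chosen after that, the largest rise among those measured was 0.52. Tyrobp, Ptprc, Laptm5 and Cd52 were not well above background in delN high, and their rise was not measured. Macrophages in the delN culture are thus an unlikely source, but only by the later test, and Lyz2, not among the 8, rose by 3.99 ± 0.071. The genotype, and differences between the cultures in growth, medium or chromosomes, remain open and untested.

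The p53 targets were lower in delN cells at both densities (medians −1.31 and −1.07), but did not pass with an estimated correlation (adjusted p = 0.46 and 0.328). Normalization as the whole cause is argued against by a list median of −0.98 or further from 0 over 4 normalizations and both densities. Loss of the surrounding genomic regions is argued against for the 22 targets lower at both densities taken as a set. The median over these targets of the median of their 10 nearest measured genes was −0.11 at low and −0.090 at high density. This value cannot decide for single targets, or for a loss limited to a target itself. Less Trp53 mRNA may be the cause, but its probes disagree: the probe starting at 69405827 differed by −4.28 at low density (at least 19.2-fold, adjusted p = 8.55e-07), and the probe starting at 69396652 by −0.13 (adjusted p = 0.17), so the amount of Trp53 mRNA stays open. With 0 genotypes on a slide that held both, slide and scan cannot be told apart from genotype, which was not tested as a cause.

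Transcripts of the sex chromosomes and the medians of whole autosomes differed between delN and WT cells. Normalization as the whole cause is argued against by Xist, which lay at −6.72 or further from 0 over 4 normalizations with delN held at the lowest value well above background, and by chromosomes 7 and 12 at −0.45 or further, relative to all genes. For these autosomes, spot position (−0.46 or further after the medians of 100 array regions were taken off) is argued against too. So is the density of a culture (0.10 at most between the densities of a genotype). A difference in growth state between the WT and delN cultures was not tested. Cultures from embryos of different sex stay an open, candidate explanation for the sex chromosomes, since the criterion set before the test was not met in full. In its direction, 4 X genes that escape inactivation had medians of −0.15 and −0.58 at low and high density. Of the Uty probes, 2 were above background only in delN and higher there at both densities. Ddx3x and Eif2s3x did not pass at low density (0.046 and −0.037, adjusted p = 0.517 and 0.528). Another Uty probe and Kdm5d, which that criterion needed (−0.035 and −0.11), were not above background in any group, WT or delN. These 2 probes thus count neither for nor against it. Differences in whole-chromosome copy number may explain chromosomes 7 and 12 (−0.51 and −0.45 at low density). No window of 20 Mb there lay nearer to 0 than −0.40 and −0.25. Whole-chromosome differences are argued against for chromosomes 14 and 8, where a window lay at 0.030 and −0.58. Differences of parts of chromosomes were not tested. On chromosome 8 the window starting at 80000001 lay at 0.71 and 0.74 at low and high density, and that starting at 120000001 at −0.58 and −0.74. On chromosome 3 the windows starting at 60000001 and 80000001 lay at 0.46 and −0.35 at low density, and at 0.28 and −0.40 at high density. DNA was not analysed here, and slide stays open.

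Other lists whose density response differed are given as medians of delN minus WT, with no explanation, and none passed with an estimated correlation (adjusted p = 0.254 to 0.576). Higher in delN were collagen and matrix genes (1.23), SRF targets (1.04), cholesterol synthesis genes (1.02), proteases (0.73), YAP and TAZ targets (0.66), TGF-beta response genes (0.57) and chondrocyte markers (0.30). Lower were NRF2 targets (−0.52), ribosomal protein genes (−0.34) and G2/M genes (−0.34).

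Named single genes with at least a 4-fold difference that were higher in delN include Ccn5 (5.47), Slc1a6 (5.40), Thbs1 (5.16), Sfrp2 (4.93), Gjb2 (4.80), Ccn2 (4.08), Cnn1 (3.32), Ccn3 (2.83), Abi3bp (2.28), Sparcl1 (2.25) and Ccn1 (2.03). Lower ones include Lum (−4.58), Bmper (−4.33), Epyc (−4.29), Blnk (−4.25), Phex (−3.64), Prl2c5 (−2.31) and Prl2c3 (−2.25). The sizes for Sfrp2, Lum, Epyc and Gjb2 depend on the background, since at least 1 group of each was not well above it (delN high for Gjb2).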

How the results depend on the processing

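The consensus correlation of limma was an alternative chosen after the data were seen, and the others were fixed before. Without the array block, the dye term, background subtraction, loess or the filter, with the stricter filter, with the consensus correlation and with each sample left out, every count of calls, of at least 2-fold changes and of shared genes stayed within 1.5 times its value.

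Requiring at least 2-fold as well left 2304 (WT density), 3341 (delN density), 1674 (difference of responses), 1986 (low density) and 2385 (high density) calls, by construction. Processed signals of Feature Extraction raised the at least 2-fold counts to 4077, 5661, 3223, 3884 and 4339, and the series table values to 4193, 5707, 3381, 3962 and 4289. Genes at least 2-fold higher with density in both genotypes then numbered 1585 and 1670, lower 991 and 983, and higher in delN at both densities 1106 and 1475, while those lower in delN numbered 1132 with the processed signals. The cause was not tested.

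With each sample left out in turn, where a lone sample is assumed to vary like the other groups, calls ranged over 11145 to 12801, 12162 to 13708, 10128 to 10661, 9946 to 11024 and 10333 to 11475 in the same order. The at least 2-fold counts ranged over 2246 to 2391, 3275 to 3463, 1639 to 1722, 1957 to 2031 and 2385 to 2430. Shared genes ranged over 879 to 912 and 498 to 539 (higher and lower with density), and 483 to 497 and 499 to 520 (higher and lower in delN).

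Of 170 list tests 57 passed, 51 to 59 with a sample left out, and 53 to 65 with other processing. With the estimated correlation between genes 0 passed (camera of limma), with an unadjusted p under 0.05 in 21. Every list call thus rests on the form with the preset correlation. The estimated form also takes its p-values from the 3 residual degrees of freedom, so the loss does not measure gene correlation alone. For ATF4 genes in the difference of responses the estimated correlation was 0.0095, under the preset 0.01. Their unadjusted p in camera still went from 2.42e-11 to 0.00674.

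Directions reversed in 8 cases. Lats2 in delN turned to 0.013 and 0.22 at low density and 0.32 and 0.54 at high density (processed signals and series table), and 0.24 at high density with the stricter filter, because another probe became the brightest. Its original probe stayed lower in delN under each, by sizes that depend on the background. The difference of responses of Cdkn1a turned to 0.31 and 0.46 with the same probe, which was near background in delN, and the ribosomal median at high density to 0.11 with the series table values, for which the cause was not tested.

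The slide block was not run, since each slide held 1 genotype. Signal over background limits the folds of Lats2, Cdkn1a, Xist and other genes given as bounds.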

Other observations

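No test in this part was chosen after its result was seen. Results of lists that the comparisons left out are given here as values. Wnt genes rose with density in delN cells in 15 of 19 cases and fell in 3 (median 1.13, adjusted p = 0.0307; adjusted p = 0.307 with an estimated correlation), a call that ended with probes above background in all 8 samples (1.29, adjusted p = 0.0971). In WT cells 9 rose and 5 fell (median 0.11, adjusted p = 0.420), and the difference had a median of 0.37 (adjusted p = 0.0960).

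Hippo pathway genes passed in no comparison, with 9 of 26 up and 14 down with density in WT (median −0.19, adjusted p = 0.236) and 11 higher and 12 lower in delN at low density (median 0.037, mean −0.20, adjusted p = 0.947). CDK inhibitor genes rose with density in 6 of 7 cases in WT (median 0.47, adjusted p = 0.0617) and 6 in delN, 1 of them Cdkn1a, whose delN signal was near background (median 0.92, adjusted p = 0.113), and did not pass as a list. Cytokine and NF-kB target genes did not pass with density in WT (15 up, 4 down, median 0.66, adjusted p = 0.0580) or between genotypes at high density (12 higher, 4 lower, median 0.36, adjusted p = 0.0680). TGF-beta response genes did not pass with density in WT (median −0.69, adjusted p = 0.0580) or delN (median 0.057, adjusted p = 0.770).

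Between the genotypes at low density, imprinted growth genes had a median of −0.82 (adjusted p = 0.219), with H19 at −3.07 ± 0.076. Hox genes had a median of −0.56 (adjusted p = 0.248) and Notch genes −0.29 (adjusted p = 0.113). Replication genes lay at −0.14 (adjusted p = 0.350) and G2/M genes at 0.024 (adjusted p = 0.889).

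Of the control lists, housekeeping genes had medians of −0.26 in WT and −0.12 in delN with density (adjusted p = 0.117 and 0.235), and −0.063 and −0.054 between genotypes (adjusted p = 0.971 and 0.948). The 5 measured sex chromosome genes were called 3 higher and 2 lower in delN at low density, with 0 not called. They did not pass as a list (adjusted p = 0.625), but the list test asks for a shared direction. That result thus does not show that these genes were unchanged. Markers of adipocytes (0.36, adjusted p = 0.304), endothelium (0.65, adjusted p = 0.144), epithelium (−0.075, adjusted p = 0.593), erythroid cells (0.0023, adjusted p = 0.932), neural and glial cells (0.24, adjusted p = 0.961) and skeletal muscle (−0.11, adjusted p = 0.567) did not pass with density in delN cells, nor in any other comparison with the preset correlation.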
